A study of Rattus norvegicus with 22 samples.

How the data were processed

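Total RNA of 22 engineered cardiac tissues was labelled with Cy3 and hybridised to 1-colour Agilent rat arrays, 1 tissue sample per array, per the labels' protocols. The deposited scanner files hold spot intensity on a linear scale, which the Feature Extraction software had background-subtracted and spatially detrended within each array but not normalized between arrays, per the file headers. The authors also deposited a table of log2 values for 27873 probes. What that table is centred on is not stated. Set against the scanner values of the same arrays, after both were centred per probe over all arrays, each of its 22 columns correlated best with its own array (r from 0.9996 to 0.9999 across probes, slope from 0.999 to 1.001), which gives the scale and direction, while the baseline stays unknown. Its column medians ran from -0.11 to 0.40. It was used as an alternative.

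The array carries 30367 probes in 42877 gene spots. Control spots and spots with an outlier flag were left out, which removed 293 probe values, and saturated spots were kept. Processed signals were taken to log2, the spots of a probe were averaged, and each array's 75th percentile was subtracted. Probes well above background on at least 4 arrays were kept (26881 probes, of which 18628 were above background on all arrays), and for each gene name the probe with the highest mean was used, leaving 23466 genes. Names came from a RefSeq table of assembly GRCr8: 18335 probes matched by accession, 2221 by symbol and 595 by synonym, and 9216 kept the name in the scanner files. No coordinates of that assembly are given. Array signal sets the precision here, together with the number of arrays per group: weak probes near background vary more, and session 2 was the dimmest.

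The headers show 3 scan sessions and 9 slides. Slides 1 to 3 of session 1 each held 1 control and 1 stretch array. Slides 4 and 5 of session 2 held stretch arrays alone. In session 3, slide 6 held 1 array of each of the 3 groups, slide 7 held 2 control arrays, slide 8 held 1 control and 2 stretch with BIRB796 arrays, and slide 9 held 3 BIRB796 arrays and 1 stretch with BIRB796 array. The spread of log2 differences between matching spots of 2 arrays was set against that between repeated spots of a probe within an array, for each of the 54 pairs of arrays of a group. Stretch replicates 4 and 5 fell below this noise and were averaged, so that the fits hold 21 samples. That step was taken after counts with all 22 arrays apart had been seen, and both forms are given in the closing section.

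Fits used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) with Benjamini-Hochberg adjustment, two-sided, on all 4 groups together, which share an estimate of the spread. A term for the array set was fixed from the file names before the data were examined. It turned out to separate session 1 from sessions 2 and 3, so a scan session term and fits within session 1 or session 3 were added. Fold changes are log2 differences with the standard error of the fit, and a gene is called at an adjusted p under 0.05. A gene not well above background on any array of a group has only a bound there: the brighter group's mean is set against the mean of, per array, the higher of the lowest signal among probes above background and the probe's own, and given as at least that many fold.

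The contrasts, their test, the gene lists and the rule for naming genes were also fixed before the data were examined. The rule took, per comparison, the 10 called genes with the largest change each way and a gene symbol, the 2 called members with the smallest p each way in each list, 12 cardiac and p38 genes whatever their values, and the 5 smallest p where no gene passed, of which the text names about 20 to 30 per comparison. Some genes taken by the rule are not reported here. The 30 lists cover sarcomere and contractile genes, cardiac stretch and hypertrophy, immediate early genes, calcium handling and ion channels, cardiac transcription factors, mitosis, DNA replication, extracellular matrix, matrix proteases, inflammatory cytokines, the p38 MAPK pathway, receptor and non-receptor tyrosine kinases, glycolysis, fatty acid oxidation, the respiratory chain, sterol synthesis, heat shock, endoplasmic reticulum stress, NRF2, TGF-beta response, focal adhesion, interferon-stimulated genes, and markers of fibroblasts, smooth muscle, endothelium, macrophages, mesothelium, erythroid cells and neural cells. Lists were tested with camera (preset correlation 0.01, and an estimated one with statmod 1.5.0 installed) and with fry, adjusted over the lists of a comparison.

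Alternatives changed a single choice at a time, apart from those named next. Normexp came with quantile scaling and the median spot signal, and array weights with a mean-variance trend. The replicate block came with the compared groups alone and without the array set term. The alternatives were no array set term, each array set alone, slide as a random block, scan session as a term, a replicate block, the compared groups alone, normexp with offset 50 and quantile scaling, quantile scaling, the array median in place of the 75th percentile, the authors' table, other filters on dim probes, the mean over a gene's probes, array weights with a mean-variance trend, and each sample left out. With normexp the median spot signal was used because 18 of the 22 files lack the mean signal. On simulated data with known changes, the fit of stretch against control recovered 52% of genes changed by 1 log2 unit and 96% of those changed by 2, among 23250 genes, with 4 false calls out of 152. For the interaction these were 18% and 65%, with 5 false calls out of 88. For session 1 alone they were 0% and 42% among 23430 genes, with 1 false call out of 43. The simulated noise was independent between arrays, with no correlation within slides, so these rates need not hold for the real fits. Same-numbered control and stretch arrays of session 1 shared a slide, and their deviations from the group means correlated at 0.507, 0.147 and 0.570, so that slide pairs them; over all samples the replicate numbers did not pair them. Other splits of the same samples, at most 100 per comparison, were fitted in the same way. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.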

Results

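Engineered cardiac tissues are cylinders of heart cells in a matrix gel, anchored at both ends so that they can be loaded like muscle. The tissues measured here were made from ventricles of Sprague Dawley rat embryos of gestational day 14.5 and kept for 7 days. From culture day 5 they were left alone (control), stretched cyclically for 48 h at 0.5 Hz and 5% elongation, given 10 µM of BIRB796 for 48 h, or given both. BIRB796 is an inhibitor of the p38 mitogen-activated protein kinase (MAPK), as the treatment protocol has it, whereas the series title speaks of tyrosine kinase. Total RNA was labelled with Cy3 and read on 1-colour rat arrays, 7 for control, 7 for stretch, 4 for BIRB796 and 4 for stretch with BIRB796. The series text calls the replicates biological without tying each to a culture or litter, so the p-values measure the spread between these samples.

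The 22 arrays were scanned in 3 sessions. Session 1 held control replicates 1 to 3 and stretch replicates 1 to 3, session 2 held stretch replicates 4 to 7 alone, and session 3 held control replicates 4 to 7 with all BIRB796 and all stretch with BIRB796 arrays. Probes well above background made up 86.1% to 93.1% of an array in session 1, 71.8% to 78.7% in session 2 and 77.4% to 84.4% in session 3, and the 75th percentile of the signal ran from 2942 to 4807, from 853 to 2468 and from 2089 to 3621. The first principal component, with 73.8% of the variance, separated session 1 from the others. Stretch replicate 7, the dimmest array with a 75th percentile of 853, stood apart on the second component. Stretch replicates 4 and 5, from different slides, differed by less than the measurement noise: their log2 signals spread by 0.047 between the arrays, against 0.089 and 0.091 between repeated spots of a probe within each. They were averaged and counted as 1 sample, which left 6 stretch samples and 21 samples in all. None of the other pairs among the 54 within groups met this, the next being control replicates 5 and 6 of slide 7 at 1.28 times the noise.

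**Figure D1:**
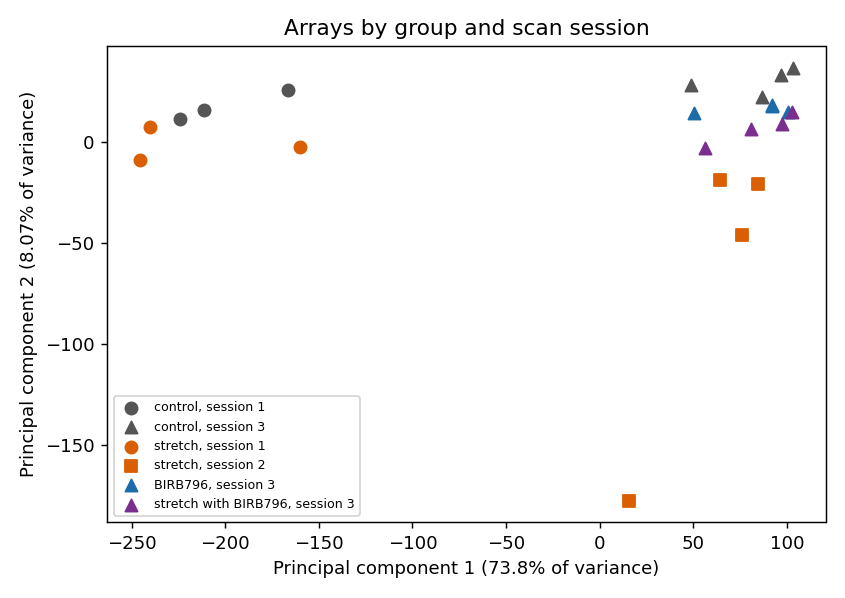
Each point is an array, placed by its first and second principal component (percent of variance on the axes), with the colour giving the group and the shape the scan session. The 6 arrays of session 1 lie between -245.5 and -160 on the first component and all others at 15.9 or higher, and stretch replicate 7 lies at -177.5 on the second.

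The first comparison asked what 48 h of cyclic stretch changed in tissue without the inhibitor. Only session 1 held both groups, so over all samples stretch of session 2 is set against control of session 3. With the session as a term limma called 0 genes, so the changes over all samples may come partly from scan sessions. Stretched tissue had more RNA of the epidermal growth factor receptor ligands Areg, which rose 8.81-fold (log2 fold change 3.14 ± 0.49 SE), and Ereg, which rose 5.81-fold (2.54 ± 0.51). The AP-1 transcription factor Fosl1 rose by 3.02 ± 0.61 and the retinal cadherin Cdhr1 by 3.12 ± 0.38. In each of these 4 genes every one of the 6 stretch samples lay above all 7 control samples (limma, adjusted p from 0.00278 to 0.0152). The natriuretic peptide genes Nppa and Nppb, which mark load on heart muscle, rose by 1.83 ± 0.46 (adjusted p = 0.0280) and 1.79 ± 0.48 (adjusted p = 0.0333). Among the genes that fell, the insulin-like growth factor binding protein Igfbp5 fell by 2.58 ± 0.51 and the exchanger Slc9a9 fell by 2.46 ± 0.37. The myosin heavy chains Myh6 and Myh7 and cardiac troponin T, Tnnt2, did not pass the test, at -0.30 ± 0.19, -0.04 ± 0.22 and 0.04 ± 0.18.

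Over all samples, some genes of 6 lists rose with stretch. Of 22 genes of the NRF2 oxidative stress response, all had positive fold changes and 10 rose (12 adjusted over the list alone), among them the antioxidant enzymes Srxn1 (2.19 ± 0.42) and Nqo1 (1.51 ± 0.34). Of 23 immediate early genes 4 rose (10 adjusted over the list alone), including Fosl1 and Fosl2 (0.82 ± 0.16). Of 23 genes of cardiac stretch and hypertrophy 7 rose (9 adjusted over the list alone), with Nppa, Nppb and the matrix glycoprotein Tnc (1.00 ± 0.31, adjusted p = 0.0499) among them. Heat shock genes rose in 4 of 19 (6 adjusted over the list alone), such as the inducible chaperone Hspa1b (1.88 ± 0.40) and the small heat shock protein Cryab (0.74 ± 0.21). Focal adhesion and actin cytoskeleton genes rose in 4 of 31 (7 adjusted over the list alone) and sterol synthesis genes in 2 of 24 (2 adjusted over the list alone), Msmo1 (0.71 ± 0.16) being the latter's smallest p. By camera with its preset correlation these 6 lists lay above other genes (adjusted p from 4.41e-05 to 0.0262), and each had an adjusted p from 0.557 to 0.630 with an estimated correlation. The median of all genes was 0.11. The dim stretch replicate 7 had the highest mean of the NRF2, heat shock and immediate early lists. Without it 17 of 22 NRF2 genes were positive, 3 of 23 cardiac stretch genes rose, and 1 of 19 heat shock genes rose, with a camera adjusted p of 0.0511 for the last list. Then 3 sterol synthesis genes rose (9 adjusted over the list alone), and adjusted over the list alone 6 immediate early and 3 focal adhesion genes rose. Other single samples moved the counts by over 1.5 times too. The NRF2 count was 3 to 6 without control replicate 4, 5, 6 or 7 or stretch replicate 1 or 6 (5 without the last), and the cardiac stretch count 0 to 4 without control replicate 3, 4, 5, 6 or 7 or stretch replicate 1 or 6 (2 without the last). Heat shock genes came to 1 or 2 without control replicate 3, 4, 5, 6 or 7 or stretch replicate 1, and immediate early genes to 7 without stretch replicate 3 or 4. Focal adhesion genes came to 1 without control replicate 4, 5 or 6 or stretch replicate 6, and to 7 without stretch replicate 3. Sterol genes came to 0 or 1 without control replicate 4, 5, 6 or 7 or stretch replicate 1 or 6 (1 without the last), and to 7 or 4 without control or stretch replicate 2. Adjusted over the list alone, with each sample left out in turn, 12 or 13 NRF2 and 7 to 11 cardiac stretch genes rose, and 5 to 14 immediate early, 4 to 11 heat shock, 3 to 9 focal adhesion and 1 to 10 sterol genes. Camera also lost the heat shock list without stretch replicate 3, the focal adhesion list without stretch replicate 6 (adjusted p = 0.0746), and the sterol list without control replicate 1 or 4 or stretch replicate 3, 4 or 6 (adjusted p up to 0.404).

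In the same fit, some markers of macrophages and vessels fell with stretch. Of 24 macrophage and leukocyte markers 23 had negative fold changes and 10 fell (21 adjusted over the list alone), with Cd68 down by -1.45 ± 0.27 and Fcer1g by -1.04 ± 0.25. Endothelial markers fell in 5 of 21 (9 adjusted over the list alone), such as the adhesion molecule Pecam1 (-1.06 ± 0.23), while 1 rose (3 adjusted over the list alone). Fatty acid oxidation genes fell in 5 of 33 (6 adjusted over the list alone), with the lipoprotein lipase Lpl at -1.47 ± 0.26 and Hadh, an enzyme of the pathway, at -0.78 ± 0.18. Among 30 inflammatory cytokines and chemokines 4 fell and 1 rose (9 and 2 adjusted over the list alone): complement C3 (-2.12 ± 0.44) and Il1b (-1.90 ± 0.44) fell and the prostaglandin synthase Ptgs2 (2.25 ± 0.52) rose. Of 17 epicardial and mesothelial markers 2 fell (3 adjusted over the list alone). Mitosis genes fell in 2 of 29 (2 adjusted over the list alone), Cenpe (-1.80 ± 0.30) being above background in 4 of 6 stretch samples. These 6 lists lay below other genes by camera (adjusted p from 7.66e-12 to 0.00761), each with an adjusted p from 0.557 to 0.630 with an estimated correlation. Fry, which asks only whether a list's own genes move in a common direction, called the macrophage and the NRF2 lists (adjusted p = 0.0401 for both). Both of fry's calls ended without stretch replicate 6 (adjusted p = 0.0514 for both). The mean of the mesothelial list was -3.61 in stretch replicate 7, against -1.25 to -0.03 in the other stretch samples and -1.02 to -0.25 in controls. Without that sample its median was -0.23 instead of -0.74, with 1 gene fallen and no call by camera (adjusted p = 0.0677). Then 6 macrophage markers, 2 endothelial markers and 3 fatty acid oxidation genes fell (14, 5 and 4 adjusted over the list alone), their lists still called by camera, and fry's adjusted p for macrophage markers was 0.0835. Without stretch replicate 6, 2 macrophage markers, 2 endothelial markers, 1 fatty acid oxidation gene, 2 inflammatory genes, 1 mitosis gene and no mesothelial marker fell (20, 14, 3, 5, 1 and 2 adjusted over the list alone). Without control replicate 4, 5 or 6 each list had 0 to 2 fallen genes (18 or 19, 9, 5 or 6, 4, 2 and 2 adjusted over the list alone). Macrophage markers also came to 5 without control replicate 3, 6 without stretch replicate 1 and 18 without control replicate 2, endothelial markers to 2 without control replicate 7, and inflammatory genes to 9 without stretch replicate 4. Fatty acid oxidation genes came to 3 without control replicate 7 or stretch replicate 1 and 10 without stretch replicate 3, mitosis genes to 1 without control replicate 7 and 4 without stretch replicate 2 or 4, and mesothelial markers to 1 without control replicate 3 or stretch replicate 1. Without stretch replicate 4, 13 mesothelial markers fell adjusted over the list alone. Camera lost the mitosis list without control replicate 3 or stretch replicate 3 (adjusted p up to 0.230) and the fatty acid oxidation list without stretch replicate 6 (adjusted p = 0.0575).

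The remaining lists held few called genes. Also below other genes by camera were calcium handling and ion channels (1 rose, the gap junction gene Gja1 at 0.95 ± 0.19, and 1 fell of 29), interferon-stimulated genes (1 rose and 2 fell of 24), receptor tyrosine kinases (3 rose and 2 fell of 42), non-receptor tyrosine kinases (1 rose and 2 fell of 27), cardiac transcription factors (1 fell of 22, Gata6 at -1.24 ± 0.26), glycolysis and hypoxia genes (0 of 32) and sarcomere and contractile genes (1 fell of 25, the atrial light chain Myl7 at -1.19 ± 0.30). Their adjusted p ran from 0.000471 to 0.0341, and from 0.557 to 0.729 with an estimated correlation. Both kinase lists were lowest in stretch replicate 7 and not called without it (adjusted p = 0.265 and 0.172). The mean of the sarcomere list was 2.79 in stretch replicate 6, against 4.28 to 4.97 in the other stretch samples and 3.83 to 4.94 in controls. Without that sample its median was 0.23 instead of -0.12, above the 0.13 of all genes, and camera did not call it (adjusted p = 0.569), nor without control replicate 2 or 7 or stretch replicate 2. Glycolysis genes lost the call without control replicate 1 or stretch replicate 4 or 6 (adjusted p up to 0.175), and cardiac transcription factors without control replicate 7 or stretch replicate 6 (adjusted p up to 0.0655). Adjusted over the list alone, 1 rose and 1 fell, 1 rose and 2 fell, 4 rose and 4 fell, 2 rose and 5 fell, 1 fell, 0 and 1 fell, in that order. In the 11 lists that camera did not call, 2 rose and 3 fell of 20 fibroblast markers (3 and 3 adjusted over the list alone), with the receptor Pdgfra at -1.69 ± 0.46, and 3 rose and 2 fell of 26 matrix proteases and inhibitors (3 and 5 adjusted over the list alone), with Plaur at 1.68 ± 0.39 and Timp1 at 1.06 ± 0.29. Of 27 TGF-beta response genes 3 rose and 2 fell (4 and 3 adjusted over the list alone), with the activin subunit Inhba at 1.87 ± 0.35, and of 35 extracellular matrix genes 2 rose and 4 fell (3 and 4 adjusted over the list alone). Smooth muscle and pericyte markers had 2 risen and 1 fallen of 19 (4 and 2 adjusted over the list alone), p38 MAPK pathway genes 2 and 1 of 33 (7 and 4 adjusted over the list alone), and neural and glial markers 2 and 1 of 20 (3 and 1 adjusted over the list alone). No smooth muscle marker rose without control replicate 3, 4, 5, 6 or 7 or stretch replicate 1 or 7, and adjusted over the list alone 1 to 3 p38 genes rose without control replicate 2, 4, 5 or 6 or stretch replicate 1, 6 or 7. A single gene fell in the respiratory chain (of 36) and in DNA replication (of 30), and a single gene rose among erythroid markers (of 16) and among endoplasmic reticulum stress and ATF4 genes (of 23), with 1, 1, 1 and 0 adjusted over the list alone. Camera called some of the 11 lists when a sample was left out. Without stretch replicate 6 these were, below other genes, extracellular matrix (adjusted p = 0.0175, 0 rose and 2 fell), matrix proteases (0.0223, 0 and 0) and TGF-beta response genes (0.0425, 1 and 0), with 0 and 3, 3 and 6, and 3 and 2 adjusted over the list alone. Extracellular matrix genes were also called without control replicate 4 (0.0444), DNA replication genes without stretch replicate 7 (0.00670) and the respiratory chain without control replicate 3 or stretch replicate 3 or 7 (0.000715 to 0.0445), all below other genes, and smooth muscle markers, above them, without stretch replicate 3 (0.0416). Among all lists of this paragraph, those called and those not, at most 2 genes of a list rose and at most 2 fell without control replicate 4, 5 or 6 or stretch replicate 6, and at most 7 and 6 without any one sample. Without control replicate 3, 14 calcium handling genes fell adjusted over the list alone, and without stretch replicate 6, 10 receptor tyrosine kinases.

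Over all 23466 genes, 2055 passed the test between stretch and control (limma, 1188 higher and 867 lower), 664 of them by at least 2-fold. Scaling by the array median gave 589 higher and 635 lower. In all, 7028 genes had an unadjusted p under 0.05, where 1173 lie by chance. Slide as a random block gave 393, and control replicates 5 and 6 averaged gave 303. Only session 1 held both groups, so a fit with the session as a term rests on the same 3 control and 3 stretch arrays as session 1 alone. Limma called 0 genes in both forms (751 and 675 at an unadjusted p under 0.05), and 0 in session 1 with slide as a block (1084). On simulated data the fit of session 1 recovered 0% of genes changed by 1 log2 unit and 42% of those changed by 2, among 23430 genes. Changes of 1 unit were thus not detected in that setting, which left out the pairing of arrays by slide. Of the 5919 genes called in sessions 2 and 3 alone, 72.4% had the same sign in session 1, with a median of 0.14 in that direction against a median size of 0.98. In session 1 Nppa was higher by 1.30 ± 0.61 and Nppb by 1.46 ± 0.78 (limma, adjusted p = 1), Fosl1 by 1.61 ± 0.29, the macrophage mannose receptor Mrc1 was at -1.46 ± 0.26 and the Wnt antagonist Sfrp2 at -1.65 ± 0.26. Macrophage markers had a median of -0.65 there with 23 of 24 negative, and NRF2 genes one of 0.27 with 19 of 22 positive. With single arrays left out the macrophage median ran from -1.01 (without control replicate 2) to -0.34 (without control replicate 3), and the NRF2 median from 0.23 to 0.38. The mean of the macrophage list was lower in stretch than in control on slides 1 and 3 (1.03 against 1.81 and 0.73 against 2.29) and higher on slide 2 (1.52 against 1.11). That of the NRF2 list was higher in stretch on slides 1, 2 and 3 (2.07 against 1.56, 1.82 against 1.77 and 2.10 against 1.51). The sarcomere, calcium handling and glycolysis lists turned positive there, with medians of 0.29, 0.10 and 0.12. Without control replicate 3 these medians were 0.007, -0.13 and -0.03, and they stayed positive without any other single array of session 1. Ptgs2, Srxn1 and Pdgfra had their extreme stretch value in the dim stretch replicate 7. Leaving out single samples gave between 289 genes (without control replicate 5) and 4694 (without stretch replicate 3).

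The next comparison asked what BIRB796 changed in unstretched tissue, where 4 control and 4 BIRB796 arrays shared session 3. In that session the embryonic and fast skeletal myosin genes Myh3 and Myh1 rose by 2.76 ± 0.31 and 2.63 ± 0.32, the cartilage matrix genes Col10a1 and Acan by 3.1 ± 0.55 and 2.56 ± 0.51, and the BMP antagonist Grem1 by 2.28 ± 0.35. The protease gene Prss3bl1 rose by 3.1 ± 0.50 and the matrix protein gene Smoc1 by 2.19 ± 0.37. The glutamate receptor Grm8, not well above background on any control array, was at least 5.22-fold higher. Col10a1 and Smoc1 were above background in 2 of 4 control arrays, and Grm8, Col10a1 and Tpm2 had 1 BIRB796 array, replicate 1, far above the others. The mucin Muc16 fell by 2.95 ± 0.56, being above background in 1 of 4 BIRB796 arrays, and the growth factor Wnt2b by 2.44 ± 0.46. The macrophage lectin Clec10a fell by 2.37 ± 0.51, measured above background on 3 of 4 control and 1 of 4 BIRB796 arrays and lowest in control replicate 7. The sizes of the falls of Muc16 and Clec10a rest mostly on inhibitor values near background and are uncertain. All of these had limma adjusted p from 0.0204 to 0.0454.

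Smooth muscle and mesothelial markers moved apart under BIRB796. Of 19 smooth muscle and pericyte markers 6 rose (15 adjusted over the list alone), with the contractile genes Actg2 (2.04 ± 0.34) and Myh11 (1.65 ± 0.28) at 4.10-fold and 3.13-fold. Of 17 epicardial and mesothelial markers 16 were negative and 4 fell (16 adjusted over the list alone), with the keratins Krt7 at -2.03 ± 0.35 and Krt19 at -1.62 ± 0.28. The list medians were 0.91 and -1.15, and camera called both (adjusted p = 2.62e-09 and 9.01e-13), with adjusted p = 0.354 for both with an estimated correlation. Extracellular matrix genes rose in 5 of 35 (10 adjusted over the list alone), for example elastin, Eln (0.91 ± 0.14), and its cross-linking enzyme Loxl1 (0.75 ± 0.12), with adjusted p = 0.388 with an estimated correlation. Focal adhesion and actin cytoskeleton genes rose in 4 of 31 (15 adjusted over the list alone), with the tropomyosin Tpm2 at 1.33 ± 0.20 and an adjusted p = 0.354 with an estimated correlation. All 29 mitosis genes were positive and all 24 macrophage markers negative, and 0 of either passed limma's test, with 8 and 0 adjusted over the list alone (adjusted p = 0.388 for both with an estimated correlation). Counts over all genes rested on single arrays. Without control replicate 4, 5 or 6 or BIRB796 replicate 2 or 4 limma called no smooth muscle, mesothelial, matrix or focal adhesion gene in the direction given, without BIRB796 replicate 1 it called 1 focal adhesion gene, without BIRB796 replicate 3 it called 3, 2, 1 and 1, and without control replicate 7 it called 14, 11, 12 and 11. With single arrays left out these were 13 to 15, 15 or 16, 8 to 14 and 11 to 15 adjusted over the list alone. So adjusted, 14 mitosis genes rose without BIRB796 replicate 4 and none without any other one array, and 22 macrophage markers fell without control replicate 7 (12 over all genes).

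Single genes of other lists also changed with BIRB796 in session 3. Agt, the angiotensin precursor, rose by 1.37 ± 0.20, the cardiac LIM protein gene Fhl1 by 0.93 ± 0.20 and Tgfb3 by 1.01 ± 0.22. Bmp2 fell by 0.65 ± 0.14, the glycolytic aldolase Aldoc by 0.73 ± 0.11 and Npr3, a clearance receptor for natriuretic peptides, by 0.98 ± 0.19. In the p38 pathway Map2k6, a kinase that activates p38, rose by 0.67 ± 0.14 and Mapk12, a p38 isoform, fell by 0.84 ± 0.19, 2 of 33 genes (3 adjusted over the list alone), but 4 without control replicate 7 and none without any other one array (7 for the former and 0 to 2 for the latter adjusted over the list alone). The p38 kinase gene Mapk14 was at 0.14 ± 0.07, with control replicate 7 apart from the other controls, and its substrate Mapkapk2 at 0.09 ± 0.07, neither past the test. Nppa (1.35 ± 0.47, limma adjusted p = 0.152), Nppb (1.71 ± 0.55, adjusted p = 0.124), Myh6 (-0.05 ± 0.11), Myh7 (0.14 ± 0.16) and Tnnt2 (0.00 ± 0.12) did not pass.

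Within session 3, 461 genes passed between BIRB796 and control (limma, 235 higher and 226 lower), 170 by at least 2-fold. Scaling by the array median turned this to 282 higher and 126 lower. Over all 21 samples limma called 0 genes (1389 at an unadjusted p under 0.05), the 5 smallest p belonging to Myh1 (2.60 ± 0.42), Krt19 (-1.53 ± 0.26), the polarity gene Insc (1.87 ± 0.32), the lectin Reg3g (-1.88 ± 0.33) and Tent5c (-1.13 ± 0.20), each with an adjusted p of 0.0837. With the session as a term the count was again 0 (1546). The session 3 count rested on single arrays: it was 0 with control replicates 5 and 6 averaged (3270 at an unadjusted p under 0.05), 0 without the 4 arrays of slide 9 (3206), and 97 with slide as a random block. It lay between 0 and 2337 when single arrays were left out, the 2337 without control replicate 7, which lay apart from the other controls for Krt19 and Clec10a.

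**Figure D2:**
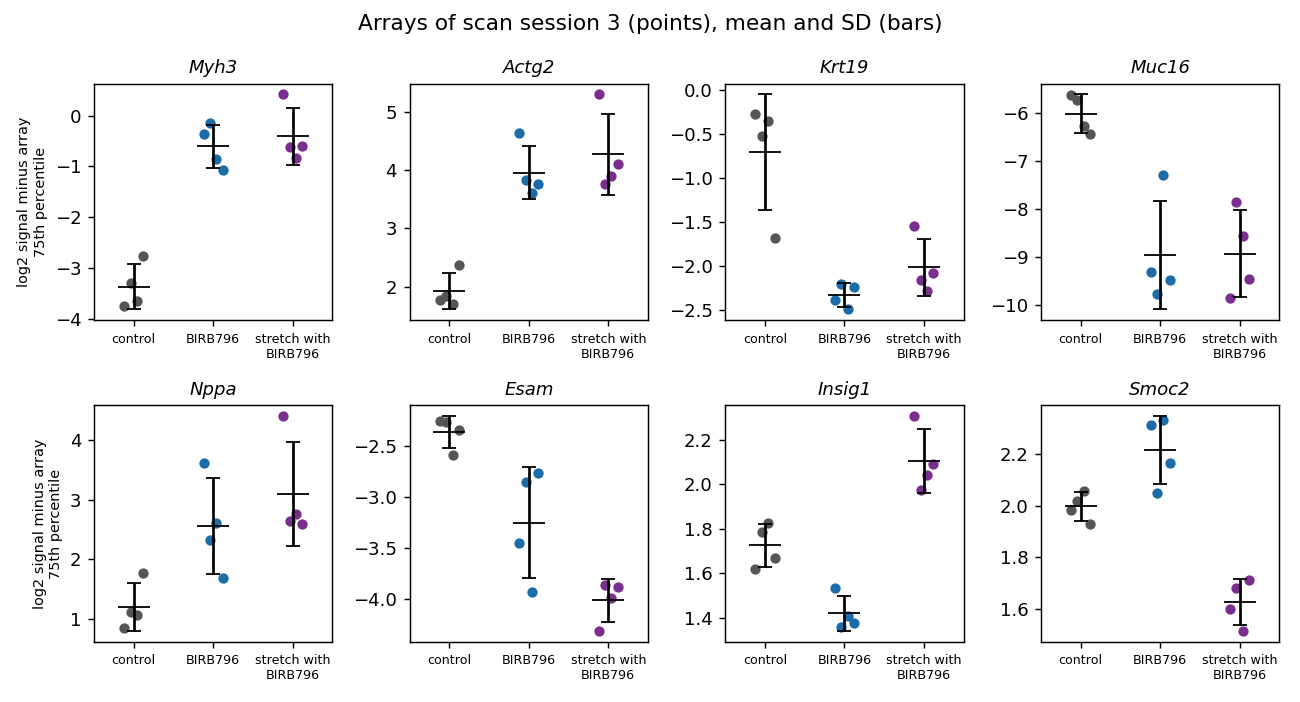
Points are the session 3 arrays of each group (4 per group), bars the mean and SD, and the vertical axis the log2 signal minus the array's 75th percentile. Myh3, Actg2 and Muc16 separated control from both inhibitor groups, Krt19 overlapped only in control replicate 7, Esam was lowest on average with both treatments, and Insig1 and Smoc2 differed between BIRB796 with and without stretch.

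The comparison of stretch with BIRB796 against stretch asked what the inhibitor changed in stretched tissue. No scan session held both groups, so the contrast over all samples is mixed with the scan session. With the session as a term limma called 0 genes. Genes lower with the inhibitor included the matrix metalloproteinase Mmp7 (-3.86 ± 0.63, above background in 1 of 4 inhibitor arrays, so that the size is uncertain), the aldo-keto reductase Akr1b8 (-3.26 ± 0.66), Cdhr1 (-3.0 ± 0.48) and the potassium channel Kcnn4 (-2.36 ± 0.42). The chemokine receptor Ccr1, the keratin Krt13 and the calcitonin gene Calca were not well above background on any inhibitor array and were at least 2.35-fold, 3.28-fold and 4.20-fold lower. Higher with the inhibitor were Cenpe (2.55 ± 0.37), the mast cell and basophil protease Mcpt8 (2.33 ± 0.40, but -0.34 ± 0.84 with a replicate block), Tgfb2 (1.70 ± 0.34) and the angiotensin receptor Agtr2, which was at least 1.99-fold higher and not above background in any stretch sample. Stretch with BIRB796 replicate 1 was far above the others for Agtr2. All of these had limma adjusted p from 0.0203 to 0.0482. Nppa and Nppb did not pass, at -0.14 ± 0.58 and 0.13 ± 0.61.

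Few members of the gene lists passed in this comparison. Immediate early genes fell in 2 of 23 (6 adjusted over the list alone), the phosphatase Dusp6 (-1.02 ± 0.22) and Fosl2 (-0.93 ± 0.20), and erythroid markers in 2 of 16 (3 adjusted over the list alone), Ahsp (-0.92 ± 0.20) and the embryonic globin Hbz (-1.58 ± 0.38). Mitosis genes rose in 2 of 29 (6 adjusted over the list alone), Cenpe and Top2a (0.89 ± 0.20). The 3 lists had adjusted p = 0.634 with an estimated correlation, against 1.02e-05 to 0.00289 with the preset one. Without stretch replicate 7, 1 immediate early gene and 1 erythroid marker fell, without stretch replicate 1, 1 erythroid marker, and without stretch replicate 3, 4 of each. Without stretch replicate 4 or 6 or any one inhibitor array no gene of those lists fell. Mitosis genes came to 4 without stretch replicate 3, to 1 without stretch replicate 4 or 6 or stretch with BIRB796 replicate 1, and to none without its replicate 2, 3 or 4. Adjusted over the list alone, 4 to 16 immediate early, 3 to 6 erythroid and 3 to 12 mitosis genes passed with single samples left out. Single called members of other lists were the endothelial adhesion gene Esam (-1.12 ± 0.25, lowest among stretch samples in replicate 7), the transcription factor Gata6 (1.49 ± 0.33) and the neurotrophin receptor Ntrk2 (1.5 ± 0.34).

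In all, 293 genes passed between stretch with BIRB796 and stretch (limma, 147 higher and 146 lower), 177 by at least 2-fold. Normexp with quantile scaling gave 260 higher and 166 lower, and scaling by the array median 67 and 34. No scan session held both groups. With the session as a term, a fit that takes stretch from the 3 arrays of session 1 and passes through the controls, limma called 0 genes (565 at an unadjusted p under 0.05). Slide as a random block gave 0 (3229), control replicates 5 and 6 averaged gave 96, and single samples left out gave between 0 (without stretch with BIRB796 replicate 2, 3 or 4) and 1721 (without stretch replicate 3).

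The effect of stretch in the presence of BIRB796 could be read within session 3, 4 arrays against 4. The fatty acid desaturase Scd rose by 1.01 ± 0.12 (2.01-fold), Insig1, a sterol sensor, by 0.69 ± 0.09, and the carotenoid oxygenase Bco1 by 0.78 ± 0.10. Prss46 (0.98 ± 0.11), Ildr2 (0.73 ± 0.08) and Styx (0.63 ± 0.08) also rose. The matrix gene Smoc2 fell by 0.59 ± 0.08. In all 7 genes the groups did not overlap (limma, adjusted p from 0.0290 to 0.0461). All 24 sterol synthesis genes had positive fold changes, with a median of 0.48. Of these 1 rose over all genes and 22 adjusted over the list alone. With single arrays left out 19 to 23 did so over the list alone, and over all genes 6 without BIRB796 replicate 3, 1 without stretch with BIRB796 replicate 2 and none otherwise. Camera called the list (adjusted p = 4.87e-32) and kept it with an estimated correlation (adjusted p = 0.0280). With single arrays left out the latter p ran from 0.00311 to 0.117, the call ending without BIRB796 replicate 1, 2 or 4 or stretch with BIRB796 replicate 3 or 4, while the preset correlation kept it each time. Endothelial markers were negative in 17 of 21 and macrophage markers in 23 of 24, with 0 past limma's test in either and 4 and 0 adjusted over the list alone (adjusted p = 0.180 and 0.718 with an estimated correlation). The 4 came to 7 without BIRB796 replicate 3 and to none without its replicate 2 or 4 or stretch with BIRB796 replicate 1 or 3.

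Of all genes 11 passed in session 3 (limma, 8 higher and 3 lower, or 11 and 8 with quantile scaling), and 1818 had an unadjusted p under 0.05. Over all 21 samples limma called 0 (347 at an unadjusted p under 0.05, where 1173 lie by chance), and 0 with the session as a term (427). The smallest p in that fit were those of Col10a1 (-2.76 ± 0.59), the lectins Reg3b (1.34 ± 0.30), Reg3g (1.46 ± 0.35) and Clec2d2l1 (1.41 ± 0.34), and S100a9, at least 10.2-fold higher and above background in 3 of 4 arrays with stretch, with adjusted p = 1.00. The sterol list kept its call over all samples (12 of 24 risen adjusted over the list alone, 0 over all genes, adjusted p = 0.0163 with an estimated correlation, but up to 0.0760 without replicate 1 of either group). The 12 genes came to 13 without BIRB796 replicate 3, 12 without stretch with BIRB796 replicate 2 and none without any other one array of these groups. The 11 genes of session 3 fell to 0 with scaling by the array median (1513 at an unadjusted p under 0.05), without slide 9 (1362), with control replicates 5 and 6 averaged (1649), or without BIRB796 replicate 1, 2 or 4 or stretch with BIRB796 replicate 4, and came to 23 without BIRB796 replicate 3.

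Both treatments together were set against control within session 3. Prss3bl1 rose by 4.36 ± 0.50, Myh3 by 2.97 ± 0.31, Actg2 by 2.35 ± 0.34 and the intercalated disc gene Xirp2 by 2.10 ± 0.33. Nppa rose by 1.89 ± 0.47 (limma, adjusted p = 0.0383) and Nppb by 2.04 ± 0.55 (adjusted p = 0.0479), with stretch with BIRB796 replicate 1 far above the others for Nppa. Mmp7 fell by 3.37 ± 0.74, with the same doubt about its size, and Il1a by 2.57 ± 0.66, while Muc16 and Clec10a, not well above background on any array with both treatments, were at least 2.88-fold and 3.29-fold lower. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 0.45 ± 0.09. Myh6 (0.10 ± 0.11), Myh7 (0.21 ± 0.16) and Tnnt2 (0.07 ± 0.12) did not pass.

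Vessel, immune and mesothelial markers fell and smooth muscle, matrix and sterol genes rose with both treatments in session 3. Of 21 endothelial markers 11 fell (13 adjusted over the list alone), with Esam at -1.65 ± 0.23, the nitric oxide synthase Nos3 at -1.07 ± 0.18 and the receptor Kdr at -0.83 ± 0.17. Of 24 macrophage markers 12 fell (22 adjusted over the list alone), with Adgre1 at -1.25 ± 0.23 and Aif1 at -0.90 ± 0.17, and complement C3 was at -1.33 ± 0.28. Mesothelial markers fell in 6 of 17 (13 adjusted over the list alone), fatty acid oxidation genes in 6 of 33 (8 adjusted over the list alone) and glycolysis genes in 4 of 32 (15 adjusted over the list alone), the glucose transporter Slc2a1 at -0.65 ± 0.13. Sterol synthesis genes rose in 12 of 24 (14 adjusted over the list alone), with Fdps at 0.58 ± 0.09 and Lss at 0.52 ± 0.08. Smooth muscle markers rose in 8 of 19 (14 adjusted over the list alone), with Tagln at 1.22 ± 0.21, extracellular matrix genes in 10 of 35 (15 adjusted over the list alone), with Fbln5 at 1.53 ± 0.28 and Loxl1 at 0.76 ± 0.12, and focal adhesion genes in 9 of 31 (17 adjusted over the list alone). Camera called all 9 lists (adjusted p from 8.78e-13 to 3.91e-06), each with an adjusted p from 0.120 to 0.274 with an estimated correlation, and fry called each (adjusted p from 0.00169 to 0.0114). Without control replicate 4, 5 or 6 each list had 0 to 4 genes so called over all genes, and without control replicate 7 it had 7 to 21. With single arrays of both treatments left out macrophage markers came to 2 to 4, mesothelial markers to 1 to 5, fatty acid oxidation genes to 2 to 6, glycolysis genes to 2 to 4 and the other 5 lists to 3 to 11. Adjusted over the list alone, 12 to 14 endothelial, 17 to 23 macrophage, 13 to 15 sterol and 13 or 14 smooth muscle genes passed with single arrays left out, and 6 to 14 mesothelial, 6 to 10 fatty acid oxidation, 4 to 15 glycolysis, 10 to 24 matrix and 11 to 19 focal adhesion genes. Other called genes were the p38 isoform Mapk12 (-1.01 ± 0.19), the receptors Fgfr3 (0.94 ± 0.18) and Axl (0.76 ± 0.16) and the transcription factor Hey2 (1.36 ± 0.35). Fbln5 and Kdr in stretch with BIRB796 replicate 1, Nos3 in replicate 3, and C3 and Clec10a in control replicate 7 lay apart from their groups.

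In session 3, 1777 genes passed (limma, 728 higher and 1049 lower), 450 by at least 2-fold, and 5786 had an unadjusted p under 0.05. Over all 21 samples 3 genes passed (1857 at an unadjusted p under 0.05): the glycosyltransferase Mgat5b rose by 2.25 ± 0.32 and Esam fell by 1.69 ± 0.24 (adjusted p = 0.0165 for both), and the locus LOC686809, named here after its value was seen, fell by 0.94 ± 0.14 (adjusted p = 0.0216). With quantile or median scaling 2 rose and 1 fell instead of 1 and 2. Esam was lower on all 4 arrays with both treatments than on any control array, and the endothelial list held over all samples (adjusted p = 0.0394 with an estimated correlation, median -0.71), with 1 of 21 fallen and 8 adjusted over the list alone (none without control replicate 4 or 5 or stretch with BIRB796 replicate 3 or 4, and 6 to 8 over the list alone with single samples left out). That p ran from 0.0260 to 0.163 with single samples left out, the call ending without control replicate 1, 3 or 7 or stretch with BIRB796 replicate 1 or 3. With the session as a term 21 passed. The session 3 count was 179 with control replicates 5 and 6 averaged, 5 without slide 9, and between 108 (without control replicate 5) and 3799 (without control replicate 7) with single arrays left out.

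The interaction term asked whether stretch acted differently with BIRB796 than without. Over all samples it is mixed with the scan session, since stretch of session 2 is set against control of session 3. Limma called 0 genes (1757 at an unadjusted p under 0.05), and 0 with the session as a term (303), where stretch without the inhibitor again comes from session 1. The smallest p were those of Lbp (1.36 ± 0.28), Muc2 (2.57 ± 0.53), Akr1c14 (2.94 ± 0.61), Cdhr1 (-2.94 ± 0.62) and Ptn (1.85 ± 0.41), each with an adjusted p of 0.639. Lbp had a low outlier in stretch replicate 3 and Ptn a high one in control replicate 3. For Nppa the interaction was -1.29 ± 0.75 and for Nppb -1.45 ± 0.78, neither past the test. By camera 13 lists differed, led by immediate early genes, all 23 of them negative with a median of -0.72 (adjusted p = 2.72e-06), macrophage markers at 0.64 (adjusted p = 1.53e-05) and mesothelial markers at 0.96 (adjusted p = 7.08e-05). Each of the 13 had an adjusted p = 0.659 with an estimated correlation. The dim stretch replicate 7 had the highest mean of the immediate early list (1.30, the next stretch sample at 0.25) and the lowest of the mesothelial list (-3.61, the next at -1.25). Without it the 3 medians were -0.41, 0.32 and 0.37 (adjusted p = 2.66e-05, 0.00246 and 0.00479), and 22 of the 23 immediate early genes were negative. These 3 lists kept camera's call with each sample left out, and the sarcomere, calcium handling, mitosis, heat shock, focal adhesion and interferon lists did not. The sarcomere and calcium handling lists changed sign with the session as a term. Across genes, which are not independent replicates, stretch effects with and without BIRB796 correlated at r = 0.20 (covariance 0.030) against -0.001 (-0.0001) in simulations without effects. Taken within sessions, the effect in session 1 against that under BIRB796 in session 3, r was 0.133 (covariance 0.0116), and over all samples it was 0.0564 without stretch with BIRB796 replicate 1. BIRB796 effects with and without stretch correlated at r = 0.40 (covariance 0.084) against 0.14 (0.018), where the fitted array set term ties the errors.

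**Figure D3:**
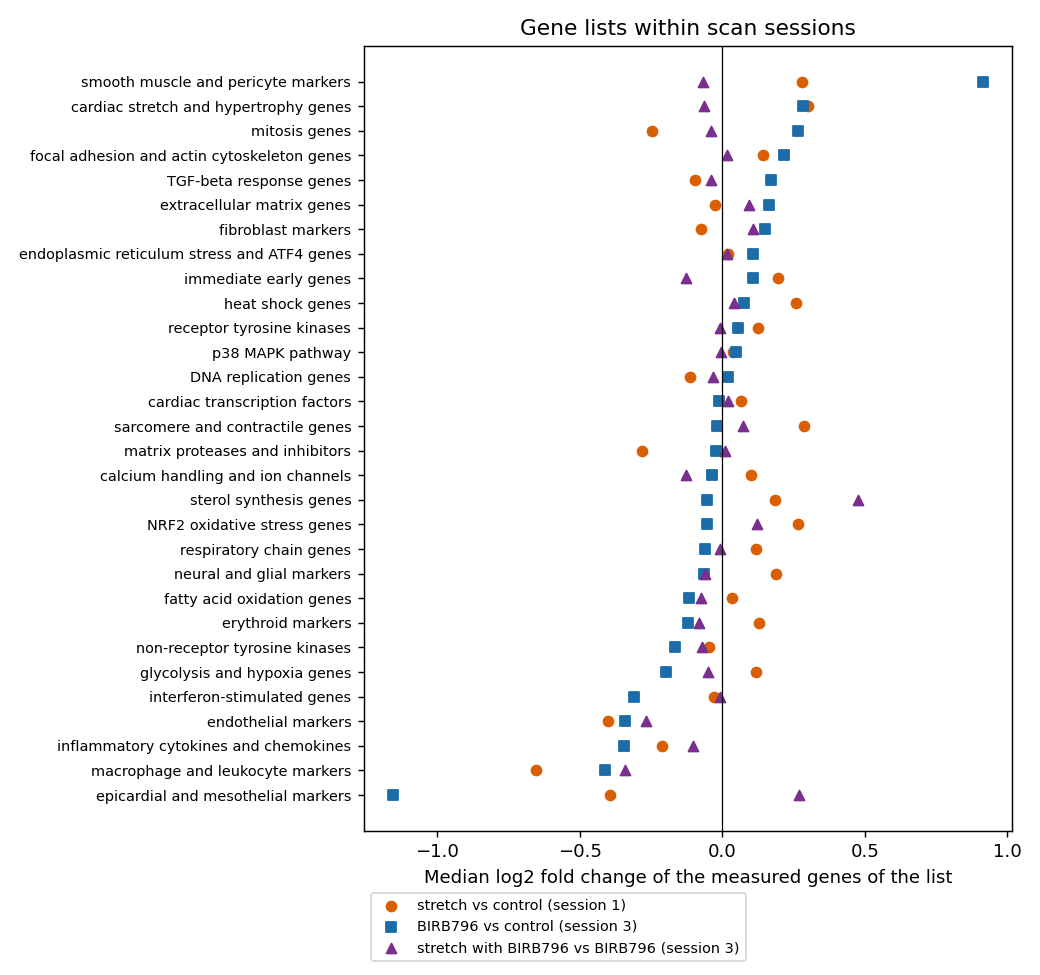
For each gene list the point is the median log2 fold change of its measured genes within a scan session: stretch against control in session 1, BIRB796 against control in session 3, and stretch with BIRB796 against BIRB796 in session 3. Under BIRB796 smooth muscle markers lay at 0.91 and mesothelial markers at -1.15, and sterol synthesis genes lay at 0.48 for stretch under BIRB796.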

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

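The tests of the dim array and of the share of heart muscle cells, the fits within a session, the list tests with samples left out, the splits by slide pairs and the averaging of near-identical arrays were chosen only after results had been seen, and so was the reading of the session test as open.

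Of 392 sets of samples examined, 35 (8.93%) held a sample far from the others, measured by its gap to the next sample over the whole range of the group; chance gives about 1 in 20. Stretch replicate 7, the dimmest array, was highest for Ptgs2 (0.684), Srxn1 (0.642), heat shock genes (0.687) and NRF2 genes (0.728), and lowest for Pdgfra (0.638), Esam (0.688), receptor tyrosine kinases (0.636), non-receptor tyrosine kinases (0.671) and mesothelial markers (0.658). Stretch with BIRB796 replicate 1 was highest for Agtr2 (0.873), Nppa (0.907), Fbln5 (0.936), Myh7 (0.857) and for the means of the cardiac stretch (0.867), mitosis (0.930), TGF-beta (0.847) and focal adhesion lists (0.839), and lowest for Kdr (0.957). Replicate 3 of that group was lowest for Nos3 (0.930) and highest for macrophage markers (0.843). BIRB796 replicate 1 was highest for Col10a1 (0.858), Grm8 (0.972) and Tpm2 (0.879) and lowest for interferon-stimulated genes (0.836), and BIRB796 replicate 3 was highest for the respiratory chain (0.915). Control replicate 7 was lowest for Krt19 over all controls (0.812) and, within session 3, lowest for Clec10a (0.857) and C3 (0.940) and highest for Mapk14 (0.875). Control replicate 3 was highest for Ptn (0.570) and lowest for sarcomere (0.569) and glycolysis genes (0.655), control replicate 2 was highest for sterol synthesis genes (0.817), stretch replicate 3 was lowest for Lbp (0.667), and stretch replicate 6 was lowest for sarcomere genes (0.680). The replicate 1 arrays of both inhibitor groups shared slide 6 with control replicate 4.

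The effect of stretch on 13 gene lists differed with and without BIRB796 by camera's test of the interaction with its preset correlation. Without the inhibitor that test sets stretch of session 2 against control of session 3, whereas under BIRB796 both groups lie in session 3. The interaction is thus mixed with the scan session. The adjusted p were 2.72e-06 for immediate early genes, 1.53e-05 for macrophage markers, 7.08e-05 for mesothelial markers, 0.000250 for sterol synthesis, 0.00163 for NRF2, 0.00364 for cardiac stretch genes, 0.0109 for interferon-stimulated genes and for calcium handling, 0.0117 for cardiac transcription factors, 0.0214 for sarcomere genes, 0.0250 for focal adhesion, 0.0421 for heat shock and 0.0487 for mitosis. With an estimated correlation the adjusted p was 0.659 for each. Without the dim stretch replicate 7, 15 lists passed, and heat shock did not (adjusted p = 0.285).

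The calls between stretch and control may come from scan sessions, since stretch of session 2 is set against control of session 3. Of the 5919 genes called in sessions 2 and 3 alone, 72.4% had the same sign in session 1, where both groups were scanned together. The highest of the other 9 splits of those 6 arrays gave 71.8%, and 63.6% was the highest of those that part all 3 slide pairs as the real one does, too few splits to count against session as the whole cause, which stays open. Without the dim stretch replicate 7 there were 1539 genes against 2055, which argues against that array as the cause of the count, though not for single lists such as the mesothelial one. Stretch itself stays an open explanation, which the 6 arrays of session 1 are too few to settle.

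The rise of smooth muscle markers and fall of mesothelial markers with BIRB796 in session 3 could come from slides, which were not balanced over the groups. With slide as a fixed block the difference between the list means was 2.15 ± 0.79 against 2.17 ± 0.47 without it, more than 2 standard errors above 0. Only slide 6 held both groups, with 1 array each. The blocked value rests on that pair and on links through arrays with both treatments, so it argues only weakly against slide as the whole cause. A lower share of heart muscle cells would by itself raise both lists. As they were picked for moving apart, the difference of 2.17 could not test that. The means of the macrophage and endothelial lists, which it would also raise, were at -0.43 ± 0.20 and -0.28 ± 0.12. A lower share next to other changes is not excluded. With control replicates 5 and 6 averaged the difference between the smooth muscle and mesothelial means was 2.10 ± 0.53. A shift in the make-up or state of the non-muscle cells under the inhibitor is a hypothesis that was not tested. Neither the smooth muscle nor the mesothelial list passed camera with an estimated correlation.

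The rise of sterol synthesis genes with stretch under BIRB796 was weighed against slides and scaling. With slide as a fixed block the list mean was 0.53 ± 0.09 against 0.48 ± 0.06, and the list median exceeded that of all genes by 0.463 with quantile scaling and 0.474 with normexp and quantile scaling, against 0.47 with the 75th percentile. Both argue against these technical explanations, for scaling only as far as quantile scaling alters it, since one shift for all genes of an array cannot move this difference. A response of sterol synthesis to stretch is a hypothesis these values may be in line with, found and tested on the same arrays, and no other session held both groups. In session 1, without the inhibitor, the median of the list was 0.18. With single arrays left out it ran from 0.03 (without control replicate 3) to 0.31 (without control replicate 2). The list mean was lower in stretch than in control on slide 2 (0.63 against 0.95) and higher on slides 1 and 3.

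Other splits of the samples bear on chance. They exchange samples freely, although arrays of a slide are alike (correlation within slides 0.563 over all arrays and 0.255 in session 3), slides and sessions are unbalanced over the groups, and control replicates 5 and 6 are nearly alike, so a small share excludes chance only if that is set aside. For stretch against control 3 of 100 splits gave as many genes as the real 2055, the highest 4021. With slide as a random block the count was 393, and with those controls averaged 303. That highest split put 5 samples of session 1 and 1 of session 2 in the stretch arm, and its count points to a structure of the samples other than the groups. For stretch with BIRB796 against stretch 8 of 100 splits gave as many as 293, so chance was not excluded. The highest, 3166, exchanged the labels of nearly all samples, with 3 stretch samples of session 2 and 1 of session 1 in the inhibitor arm. The arrays of session 3 were all in its stretch arm. It thus parts session 2 from session 3, as the real grouping does, and cannot tell treatment from scan session. For both treatments against control over all samples 2 of 100 splits reached 3 genes, the highest other 7, but limma called 0 with those controls averaged (1406 at an unadjusted p under 0.05). At an unadjusted p under 0.05, 1 of 100 splits reached the 1389 genes of BIRB796 against control (highest other 1351), but with those controls averaged the count was 1113, below the 1173 that lie by chance, so chance was not excluded. Likewise 16 of 35 reached 347 for stretch with BIRB796 against BIRB796 (highest other 757), 20 of 100 reached 1757 for the interaction (6545, a split several times the real count) and 25 of 100 reached 2337 for the mean stretch effect of sessions 1 and 3 (6084), so chance was not excluded for these 3. Within session 3 only the real split, 1 of 35, reached the counts: 461 for BIRB796 against control (highest other 119), 11 for stretch with BIRB796 against BIRB796 (highest other 0) and 1777 for both treatments against control (highest other 1), which excludes chance for all 3 only if the arrays can be exchanged freely. With slide as a random block the counts were 97, 16 and 1667, and with those controls averaged limma gave 0 (3270 at an unadjusted p under 0.05), 0 (1649) and 179. The 10 splits of session 1 are too few for a share under 0.05; 6 of them reached the real 675, and the highest other was 4753. Of the 4 that part all 3 slide pairs, as the real one does, 2 reached it, the highest other being 775; the others part 1 pair.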

How the results depend on the processing

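The fits within a session, the array averaging, the fit without slide 9, slide as a fixed block in session 1, and the list tests with a session term or with samples left out were chosen only after the data had been seen. Except where the number of samples or genes fell, the cause was not tested for any value given here. The number of arrays limits the precision, and for weak genes the signal over background does too, most of all in session 2. All alternatives fixed beforehand were run, an array set alone only for groups with arrays in it. Counts are limma calls, and those in parentheses are genes at an unadjusted p under 0.05.

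The 2055 calls between stretch and control came to 298 with no array set term, 5919 in array set 2 alone, 393 with slide as a random block, 1224 with scaling by the array median and 303 with control replicates 5 and 6 averaged. They came to 0 with scan session as a term (751) and in array set 1 alone (675), which rest on the same 6 arrays of session 1, and with only the groups compared (4885). With stretch replicates 4 and 5 as separate arrays they were 2337. Single samples left out gave 289 to 4694: 402, 289, 313 and 910 without control replicates 4, 5, 6 and 7, and 1281, 4694, 3192 and 598 without stretch replicates 1, 3, 4 (with 5) and 6.

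For BIRB796 against control over all samples the 0 (1389) became 1 in array set 2 alone, 1 with normexp and quantile scaling, 5 with the array median, 1538 with array weights and a mean-variance trend, 260 with only the groups compared, and 0 to 51 with single samples left out, the 51 without control replicate 7. For stretch with BIRB796 against BIRB796 the 0 (347) became 7 with array weights and a mean-variance trend and 0 to 4 with single samples left out, the 4 without stretch with BIRB796 replicate 1. The 0 (1757) of the interaction became 1075 in array set 2 alone, 173 with array weights and that trend, and 0 to 59 with single samples left out, 59 without stretch replicate 3 and 1 without stretch with BIRB796 replicate 1.

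The 293 calls between stretch with BIRB796 and stretch came to 155 with no array set term, 3784 in array set 2 alone, 101 with the array median, 125 with no filter on dim probes, 579 with probes above background on all arrays, 2469 with array weights and a mean-variance trend, 1041 with stretch replicates 4 and 5 separate and 96 with control replicates 5 and 6 averaged. They came to 0 with slide as a random block (3229) and with scan session as a term (565), which takes stretch from session 1 alone. Single samples left out gave 0 to 1721: 189, 1721, 19, 44 and 135 without stretch replicates 1, 3, 4, 6 and 7, 24 without stretch with BIRB796 replicate 1, and 0 without its replicate 2 (3835), 3 (4181) or 4 (3839).

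The 3 calls between both treatments and control came to 1 with no array set term, 14 in array set 2 alone, 13 with slide as a random block, 21 with scan session as a term, 2954 with array weights and a mean-variance trend, 476 with only the groups compared, and 0 with normexp and quantile scaling (2007) or with control replicates 5 and 6 averaged (1406). Single samples left out gave 0 to 83: 5, 0, 0, 1 and 83 without control replicates 2, 4, 5, 6 and 7, and 8, 1 and 0 without stretch with BIRB796 replicates 1, 3 and 4.

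Within session 3, the 461 calls of BIRB796 against control came to 1100 with normexp and quantile scaling, 799 with probes above background on all arrays, 97 with slide as a random block, and 0 without slide 9 (3206) or with control replicates 5 and 6 averaged (3270). Single arrays left out gave 0 to 2337: 0, 0, 0 and 2337 without control replicates 4, 5, 6 and 7, and 51, 0, 127 and 22 without BIRB796 replicates 1 to 4. The 11 calls of stretch under BIRB796 came to 41 with normexp and quantile scaling, 19 with quantile scaling alone, 27 with probes above background on all arrays, and 0 with the array median (1513), without slide 9 (1362) or with control replicates 5 and 6 averaged (1649). Single arrays left out gave 0 to 23: 0, 0, 23 and 0 without BIRB796 replicates 1 to 4, and 4, 2 and 0 without stretch with BIRB796 replicates 1, 3 and 4. The 1777 calls of both treatments came to 2743 with normexp and quantile scaling, 5 without slide 9 and 179 with control replicates 5 and 6 averaged. Single arrays left out gave 108 to 3799: 240, 108, 217 and 3799 without control replicates 4 to 7, and 664, 936 and 580 without stretch with BIRB796 replicates 1, 3 and 4. In session 1, with 0 calls (675), the smallest adjusted p was 1, so arrays left out there say nothing about stability. For the mean stretch effect of sessions 1 and 3 the 0 calls (2337) came to 78 with normexp and quantile scaling, 51 with quantile scaling alone, 1 with the array median, 16 with probes above background on all arrays, 59 with slide as a random block, and 0 to 170 with single arrays left out, 4 without control replicate 1, 170 without stretch replicate 2 and 1 without stretch with BIRB796 replicate 1.

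Over all samples replicate numbers paired the samples unevenly at most. Deviations of same-numbered samples correlated between -0.181 and 0.570, with 3 of 6 pairs of control and stretch over 0.1, of which 2 correlated best with their own number. Between stretch and BIRB796, which shared no slide or session, the median was 0.147 against -0.038 for other numbers. Only between control and stretch with BIRB796 was it below, at 0.002 against 0.020. In session 1 numbers and slides of control and stretch coincided, so they cannot be told apart there. Control replicate 2 correlated better with stretch replicate 1 of another slide (0.218) than with stretch replicate 2 (0.147). With a replicate block limma called 0 genes between stretch and control (3575), 289 between BIRB796 and control, 0 between stretch with BIRB796 and stretch (9112) and 1111 between both treatments and control. These fits held only the groups compared, without the array set term. Control and stretch replicates 1 to 3 were of session 1 and all inhibitor arrays of session 3. Stretch replicates from 4 on were of session 2 and the same-numbered controls of session 3. All of these counts thus mix treatment with scan session. Mcpt8, higher by 2.33 in stretch with BIRB796 than in stretch, was at -0.34 with that block. This was the only reversal counted among named genes. Signs were compared only for genes called before or after the change. In session 1, with slide as a fixed block in place of no block, limma called 0 genes (1084) and camera 12 lists against 14, no longer sarcomere genes (adjusted p = 0.152) and non-receptor tyrosine kinases (0.108). It changed no other list call there, and with an estimated correlation or fry the count was 0 in both forms.

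Of 19 lists called between stretch and control, 0 held with an estimated correlation, fry called 2, and with scan session as a term camera called 12. The counts with camera, an estimated correlation and fry were 15, 0 and 0 for BIRB796 against control, 13, 0 and 0 for stretch with BIRB796 against stretch, 18, 1 and 1 for both treatments against control, and 13, 0 and 0 for the interaction. For stretch with BIRB796 against BIRB796 they were 3, 1 and 0, and 5 by camera with no array set term. Within session 1 they were 14, 0 and 0. Within session 3 they were 16, 0 and 6 for BIRB796, 6, 1 and 1 for stretch under BIRB796 and 21, 0 and 15 for both. For the mean stretch effect they were 13, 0 and 3. With single samples left out camera called 16 to 19 lists for stretch, 12 to 15 for BIRB796, 11 to 15 for stretch with BIRB796 against stretch, 3 to 7 against BIRB796, 16 to 18 against control and 11 to 18 for the interaction. In session 1 it called 6 to 19, in session 3 14 to 16 for BIRB796, 6 to 13 for stretch under BIRB796 and 18 to 22 for both, and for the mean stretch effect 8 to 15. The correlation of BIRB796 effects with and without stretch, 0.402, was 0.838 with no array set term and 0.290 to 0.485 with single samples left out. That of stretch effects, 0.201, was 0.0564 to 0.281 with single samples left out. For named genes the other alternatives kept the side of the threshold in 1332 cases, lost the call in 443 and gained it in 27. With single samples left out these were 1049, 469 and 10. Direction was compared only for genes called before or after the change. Genes called in neither fit may thus have changed sign within the 1332 and 1049.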

Other observations

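The 2 marker lists for fast skeletal muscle and cartilage were chosen only after Myh1, Myh3, Acan and Col10a1 had been seen to be higher with BIRB796, and the mean stretch effect of sessions 1 and 3 was added after the headers showed the sessions. The list tests with samples left out and the skeletal test with Myh2 and Myl1 put back were chosen after results had been seen.

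The effect of stretch averaged over session 1, without BIRB796, and session 3, with it, sets stretch only against arrays scanned with it. All 24 sterol synthesis genes were positive, with a median of 0.35, and 13 rose adjusted over the list alone (adjusted p = 0.166 with an estimated correlation, fry adjusted p = 0.0159). The average holds the session 3 arrays in which the sterol rise was found, so it is no separate evidence. In session 1 alone, with slide as a block, the sterol median was 0.18 against 0.08 for all genes (camera adjusted p = 0.198, fry adjusted p = 0.947). Endothelial markers were negative in 18 of 21, with a median of -0.47, and 7 fell adjusted over the list alone (adjusted p = 0.0941 with an estimated correlation, fry adjusted p = 0.0159). Of 24 macrophage markers 23 were negative, with a median of -0.48, and 4 fell adjusted over the list alone (adjusted p = 0.381 with an estimated correlation, fry adjusted p = 0.210). NRF2 genes were positive in 20 of 22, with a median of 0.18, and 6 rose adjusted over the list alone (adjusted p = 0.166 with an estimated correlation, fry adjusted p = 0.0159). With single samples left out fry's adjusted p for the sterol, endothelial and NRF2 lists reached 0.0631, their calls ending without control replicate 1 or 3 or stretch replicate 3, and fry called macrophage markers without control replicate 2 (adjusted p = 0.0284). Adjusted over the list alone, 7 sterol, 4 endothelial, 0 macrophage and 3 NRF2 genes passed limma's test without control replicate 3, and 18, 8, 19 and 8 without control replicate 2. Over all genes limma called 0 (2337 at an unadjusted p under 0.05).

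The rise of Myh1 and Myh3 with BIRB796 in session 3 raised the hypothesis of a shift in skeletal muscle genes as a whole. In 22 fast skeletal markers without Myh1, Myh3, Myh2 and Myl1, the last 2 left out because their values had been seen too, 13 were positive, the median was 0.02 and the mean -0.03, and camera with an estimated correlation gave p = 0.496, so the hypothesis stays open without evidence for it. With Myh2, not well above background on any control array, and Myl1 (-0.45 ± 0.16) put back, p was 0.626. Myh8 (-0.20 ± 0.13), the creatine kinase gene Ckm (-0.18 ± 0.15) and the muscle regulator Myog (0.04 ± 0.26) did not pass limma's test, nor did the calcium channel gene Cacna1s (1.27 ± 0.34, adjusted p = 0.0830).

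The rise of Acan and Col10a1 raised the like hypothesis for cartilage genes. In 16 other cartilage markers 14 were positive with a median of 0.21, and 2 rose and 1 fell adjusted over the list alone. Camera with an estimated correlation gave p = 0.256, which leaves the hypothesis open. Epyc (1.28 ± 0.38) did not pass limma's test over all genes. Matn3 was not well above background on any control array and was so on 2 of 4 BIRB796 arrays, while the cartilage regulator Sox9 was at 0.02 ± 0.15, Col2a1 at -0.13 ± 0.28 and Hapln1 at -0.66 ± 0.16.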
